A study of Mus musculus with 8 samples.

How the data were processed

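Genome-wide binding of the transcription factor C/EBPα was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse liver. Per the labels, there were 8 libraries in 4 groups of 2, all made with the same C/EBPα antibody, from mice fasted for 4 hours before tissue harvest. Frozen liver was crosslinked in 1% formaldehyde and nuclei were isolated before sonication, per the labels' protocols. In the first experiment, mice carrying a floxed Trib1 gene received 1.5e11 gc of an adeno-associated virus (AAV) vector, either an empty one (group Trib1_WT) or one coding for Cre recombinase (group Trib1_LSKO). In the second, wild-type mice received 1e12 gc of an empty vector (AAV_Null) or of a vector coding for C/EBPα (AAV_Cebpa). Mice were 8 to 10 weeks old.

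The authors deposited 1 list of peaks per library, with no list for pooled libraries among those used here. Each line holds a position and 1 signal value. Every peak was 200 bp wide in all 8 lists. Per the submitters' processing notes, Bowtie, HOMER and the mouse build mm9 were used. Versions, the use of an input library, the calling threshold and the treatment of duplicate reads are not given in the sources used here. Peaks on chromosome 1 reached position 197173796, beyond the last gene end on that chromosome in the GRCm38 gene table (195291439), so the lists do not use that later build. The deposited signal values were printed to 1 decimal and were whole multiples of a single step in each library, within the rounding (0.051), for at least 99.87% of peaks. The step differed between libraries, as it does when the sequence tags under a peak are scaled to a fixed library total. The inverse of the step was therefore taken as the library's relative depth. The absolute depth and the total used for scaling are not given in the sources used here. A signal value is the authors' own value for a peak. It was used only to rank, describe or filter peaks inside its own list, as a percentile in which 100 is the strongest peak, and no differential test was run on it.

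For the comparisons, a window of 200 bp was set around each peak's midpoint, and windows of all 8 libraries that overlapped by at least 1 bp were joined into sites. This gave 113353 sites from 446523 peaks, with a median width of 223 bp and a maximum of 723 bp. A library had more than 1 peak in a site in 3 cases. A site is called gained when both treated libraries and neither control library had a peak there, and lost in the reverse case. With 2 libraries per group, the exact two-sided permutation test over the 6 assignments of 4 libraries cannot go below 0.333, so no single site was tested. The numbers of gained and lost sites were therefore set beside those of the other ways of splitting the same 4 libraries into groups of 2. Directions of sites that changed in both experiments were compared with an odds ratio, its 95% interval and a two-sided Fisher's exact test. The 2 experiments have separate control libraries, so no control library enters both. The control lists still resemble each other, and a site absent from both control groups can be gained but not lost. Associations were therefore also computed within fixed control states (for instance among sites absent from all 4 control lists), and again with the roles of Trib1_LSKO and Trib1_WT exchanged. Agreement of 2 lists is the Jaccard index, the number of sites called in both divided by the number called in either. Shares of sites have 95% Wilson or exact binomial intervals, which cover counting of sites only. Chromosome shares were compared by Fisher's exact test with Benjamini-Hochberg adjustment over 80 tests (20 chromosomes, 2 comparisons, gained and lost). The labels do not say whether replicates came from separate animals, so spreads between replicates may be technical. Replicate lists shared 1.8% to 2.3% of exact peak positions, so no list was a copy of another.

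Samples, the main tests and alternatives and the rule for the sites named were fixed before the data were examined. The rule names, for each comparison, the 5 gained and the 5 lost sites with the highest mean percentile in the 2 libraries that hold them, and the 5 sites gained in both comparisons with the highest mean percentile over the 4 treated libraries. Tests of fixed gene lists, sequence motifs and promoters had also been planned. They need genes or sequence of build mm9, which were not used here, so sites are given by mm9 coordinates (1-based) and no gene was assigned to a site. Alternatives were other window sizes, the strongest 50% of each list, presence taken from the strongest 50% with absence from the full list, lists reduced to equal length (46348 peaks for the second experiment and across both, 50075 for the first), autosomes only and leaving out each library. The reading of changed sites in the single libraries of the other experiment, the tests of the Jaccard index between experiments, the associations within control states and the strength of shared sites were added after the data had been examined. So were 4 alternatives: a signal of at least 10 in every list, thinning tags at random to the shallowest library and keeping peaks with at least 10 tags, asking that no peak of the opposite group lie within 500 bp, and counting sites within pairs of the same replicate number. The code for site counting was run on simulated lists for 113353 sites with 400 sites changed in each comparison, and 100.0% of these were recovered in both. Changed sites were planted as present in both lists of one group and absent from both of the other, which is their definition. Recovery therefore checks only the joining of peaks into sites and says nothing about false calls in the real lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.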

Results

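C/EBPα, a basic leucine zipper transcription factor of hepatocytes, was mapped by ChIP-seq in mouse liver under 2 perturbations. In the first, Trib1, which encodes the pseudokinase Tribbles-1, was targeted by giving floxed mice a vector coding for Cre recombinase (Trib1_LSKO, n = 2 libraries), with floxed mice given an empty vector as controls (Trib1_WT, n = 2). In the second, wild-type mice received a vector coding for C/EBPα (AAV_Cebpa, n = 2) or an empty vector (AAV_Null, n = 2). Peak lists held 53327 and 54691 peaks in Trib1_WT, 50075 and 53072 in Trib1_LSKO, 46348 and 49052 in AAV_Null, and 59564 and 80394 in AAV_Cebpa. Relative to the shallowest library, AAV_Null replicate 1, the depth was 1.14 and 1.93 in Trib1_WT, 1.18 and 1.28 in Trib1_LSKO, 1.17 in AAV_Null replicate 2, and 1.85 and 2.27 in AAV_Cebpa. The overexpression libraries were thus deeper than both of their controls. The weakest peak listed held 7 to 8 tags in 5 libraries, 11 tags in Trib1_WT replicate 2 and AAV_Cebpa replicate 1, and 12 tags in AAV_Cebpa replicate 2. Peak lists hold no transcript or protein levels, so neither loss of Trib1 nor the amount of C/EBPα was measured here.

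**Figure D1:**
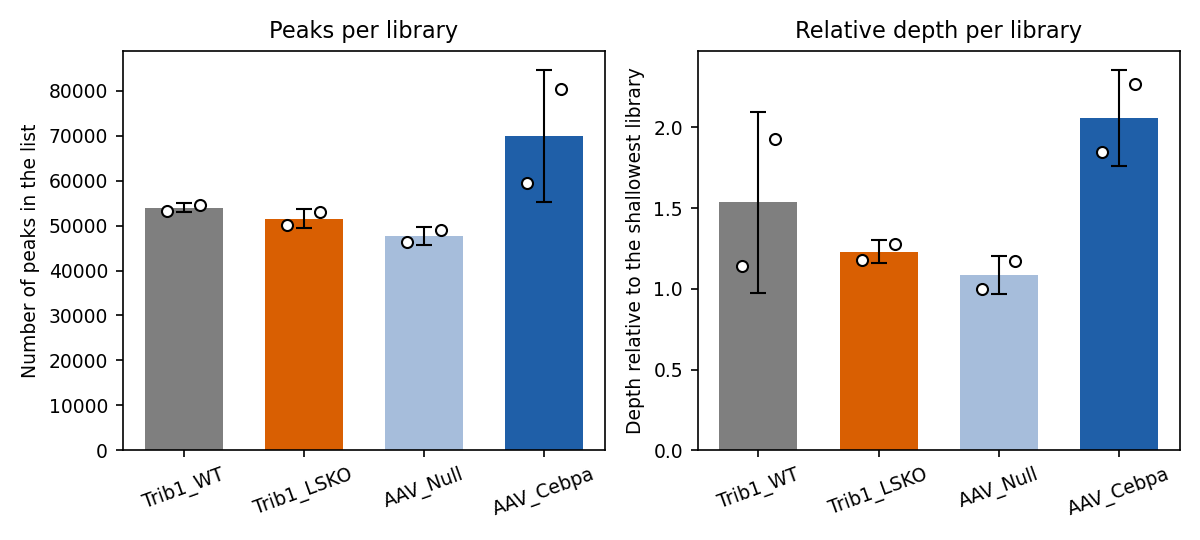
Number of peaks in the list (left) and sequencing depth relative to the shallowest library (right) for the 4 groups. Bars are means, circles are the 2 libraries of a group and error bars are SDs; the AAV_Cebpa lists, with 59564 and 80394 peaks, are the longest and come from libraries at 1.85 and 2.27 times the lowest depth.

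Replicates shared more sites with each other than with the opposite group in both experiments. The Jaccard index was 0.691 between the Trib1_WT replicates and 0.699 between the Trib1_LSKO replicates, against 0.632 ± 0.018 (SD over the 4 library pairs) between the groups, with a range of 0.615 to 0.652. It was 0.658 between the AAV_Null replicates and 0.665 between the AAV_Cebpa replicates, against 0.402 ± 0.022 between those groups (range 0.381 to 0.427). The 2 control groups, which differed in genotype and vector dose, had an index of 0.590 ± 0.017 with each other. Trib1_LSKO libraries lay closer to AAV_Cebpa than Trib1_WT libraries did, with mean indices of 0.495 ± 0.010 and 0.440 ± 0.001 (SD, n = 2 each). They lay farther from AAV_Null, at 0.553 ± 0.018 against 0.590 ± 0.018. Both differences had p = 0.333 in the exact two-sided permutation test, the smallest value that 2 against 2 libraries can give.

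**Figure D2:**
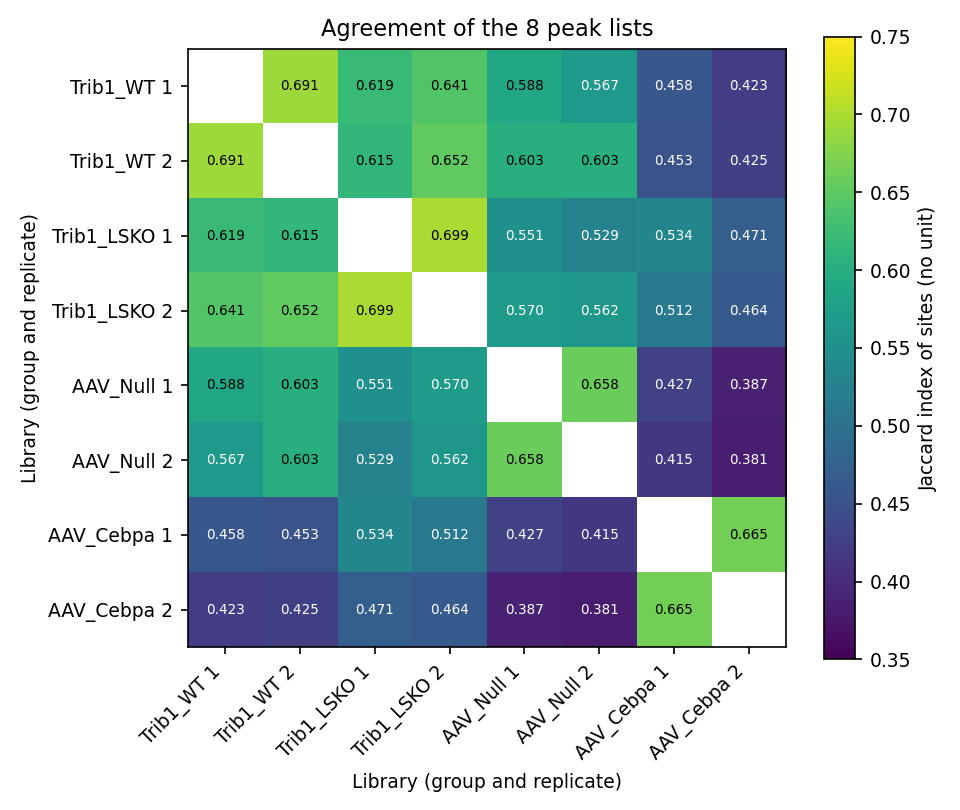
Jaccard index (sites called in both lists divided by sites called in either) for each pair of the 8 libraries, labelled by group and replicate on both axes. Values within groups are 0.658 to 0.699, and the lowest values, 0.381 to 0.427, are between AAV_Null and AAV_Cebpa.

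The first comparison asked how targeting Trib1 altered C/EBPα occupancy. Most of the sites called in both Trib1_LSKO libraries were also called in both Trib1_WT libraries (34866 of 42436, 82.2%). A further 3569 sites were gained in Trib1_LSKO and 3661 were lost, which is 8.41% and 8.29% of the sites called in both libraries of the respective group. The other ways of splitting the same 4 libraries gave 2722 and 2065 sites that differed in this manner, against 7230 for the real groups, a ratio of 2.66 to the higher of the 2. Gained sites made up 49.4% of the changed sites (95% exact binomial interval 48.2% to 50.5%). The balance moved to 54.3% after thinning tags (3829 gained, 3225 lost), to 55.3% with lists of equal length and to 57.6% with a signal of at least 10 in every list. Neither direction was favoured under all settings. With 1 library left out the definition is looser, and gained sites numbered 7612 or 7385 without Trib1_LSKO replicate 1 or 2 and 5432 or 5707 without Trib1_WT replicate 1 or 2, with 5527, 7423, 9281 and 8959 lost sites in the same order. The share of gained sites ran from 36.9% without Trib1_WT replicate 1 to 57.9% without Trib1_LSKO replicate 1. It depends on which group is left with 1 library, because sites of that group then need a peak in only 1 list. The number of peaks was 51574 ± 2119 in Trib1_LSKO and 54009 ± 964 in Trib1_WT (SD, n = 2 each; exact two-sided permutation p = 0.333, the smallest possible). The difference of -2435.5 peaks was -937.0 without Trib1_LSKO replicate 1, -3934.0 without Trib1_LSKO replicate 2, -691.5 after thinning tags to the shallowest library and 5.0 with a signal of at least 10 required.

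Changed sites of this comparison were weaker than common ones. Gained sites had a median percentile of 30.2 and 26.9 in the 2 Trib1_LSKO lists, and lost sites one of 25.8 and 24.4 in the 2 Trib1_WT lists. Sites called in all 4 libraries had medians of 63.3 to 66.3. In both lists of their group, 541 gained sites (15.2%) and 428 lost sites (11.7%) belonged to the strongest 50%.

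The strongest gained sites of Trib1_LSKO lay on chromosomes 1 and 5. In mm9 coordinates these were chromosome 1, 145748323 to 145748567, with a mean percentile of 98.1; chromosome 1, 63841012 to 63841219, with 97.3; chromosome 1, 164822251 to 164822488, with 97.2; chromosome 5, 92050320 to 92050538, with 96.9; and chromosome 1, 145828988 to 145829219, with 95.4. All 5 were also called in both AAV_Cebpa libraries, which have the longest lists, and 1 of them in both AAV_Null libraries. The strongest lost sites were chromosome 13, 35108176 to 35108417 (mean percentile 96.5 in Trib1_WT), chromosome 11, 68908556 to 68908817 (93.1), chromosome 1, 164821957 to 164822166 (93.0), chromosome 11, 86395309 to 86395510 (91.2) and chromosome 14, 66338169 to 66338379 (88.9). Of these 5, only the second was called in both AAV_Cebpa libraries. The lost site at 164821957 and the gained site at 164822251 on chromosome 1 are neighbours, and whether they are separate binding sites or a shift of the called position was not tested. Such neighbours were uncommon in this comparison: 165 gained sites (4.6%) and 190 lost sites (5.2%) had a peak of the opposite group within 500 bp. In the second experiment, 830 gained sites (3.8%) and 634 lost sites (10.5%) had one.

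The second comparison asked how extra C/EBPα altered its occupancy. In AAV_Cebpa, 22124 sites were gained and 6043 were lost, a ratio of 3.66. Gained sites were 39.6% of the 55906 sites called in both AAV_Cebpa libraries. Of the 37859 sites called in both AAV_Null libraries, 27702 (73.2%) were called in both AAV_Cebpa libraries as well. The real groups differed at 28167 sites and the other splits at 1796 and 1623, a ratio of 15.7 to the higher of these. Gained sites were 78.5% of the changed sites (95% exact binomial interval 78.1% to 79.0%), and 56.8% (12783 gained, 9713 lost) when each list was cut to the same length, a setting that takes the difference in peak number away. Without AAV_Null replicate 1 the ratio of gained to lost sites was 2.05 and without AAV_Cebpa replicate 1 it was 5.95, with 40407 gained sites in the latter case. Lost sites numbered 12252 and 10017 without AAV_Null replicate 1 and 2 and 9414 without AAV_Cebpa replicate 2. After thinning tags to the shallowest library, 18211 sites were gained and 6545 lost. The number of peaks was 69979 ± 14729 in AAV_Cebpa and 47700 ± 1912 in AAV_Null, 1.47 times as many (SD, n = 2 each; exact two-sided permutation p = 0.333, the smallest possible). The difference of 22279.0 peaks fell to 11864.0 without AAV_Cebpa replicate 2.

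**Figure D3:**
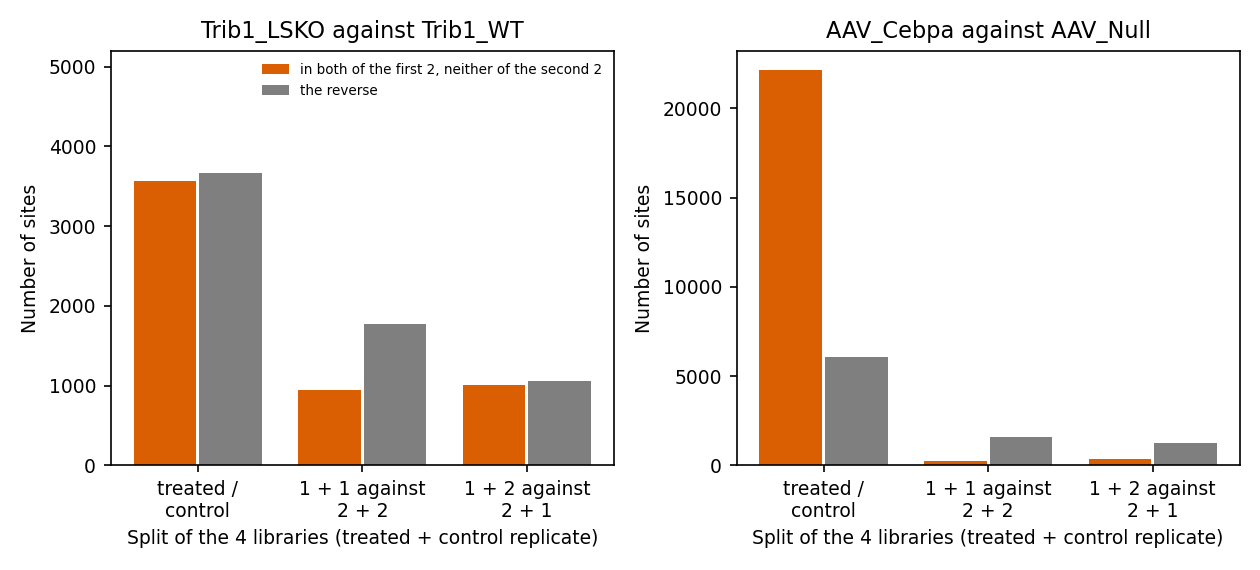
Number of sites (vertical axes, which differ in scale) called in both libraries of one side of a split and in neither of the other, for the real groups and for the 2 other splits of the same 4 libraries, which put 1 treated and 1 control replicate on each side. In the real groups the bars are gained and lost sites, 3569 and 3661 on the left and 22124 and 6043 on the right; the other splits sum to at most 2722 and 1796.

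Sites gained with the C/EBPα vector were not confined to the weak end of the lists. Their median percentile was 34.6 in AAV_Cebpa replicate 1 and 49.9 in replicate 2, and 6944 of them (31.4%, 95% exact binomial interval 30.8% to 32.0%) were in the strongest 50% of both lists. Lost sites had medians of 36.4 and 39.8 in the AAV_Null lists, and 1427 (23.6%) were in the strongest 50% of both. Common sites had medians of 66.7 to 75.8.

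The strongest gained site was on chromosome 7, 35905237 to 35905462. It ranked 5 of 59564 peaks in AAV_Cebpa replicate 1 and 2 of 80394 in replicate 2, and it was called in none of the other 6 libraries. Whether sequence of the C/EBPα vector aligns at this site, which would count vector DNA as signal there, was not examined. The next were chromosome 15, 59538695 to 59538934 (mean percentile 99.9), chromosome 12, 119958702 to 119958964 (99.8), chromosome 13, 34201544 to 34201770 (99.7) and chromosome 15, 101414064 to 101414303 (99.6). These 4 were called in both Trib1_LSKO libraries, at percentiles of 69.3 to 96.7, and only the last in Trib1_WT, at 11 and 13.5. The strongest lost sites were chromosome 17, 39984685 to 39984890 (mean percentile 99.9 in AAV_Null), chromosome 1, 90184740 to 90184976 (99.3), chromosome 4, 105868228 to 105868442 (97.8), chromosome 8, 36274603 to 36274815 (97.1) and chromosome 17, 24358317 to 24358531 (97.1). Of these 5 lost sites, 4 were called in both Trib1_LSKO libraries and 2 in both Trib1_WT libraries, and each was called in at least 1 library of both groups. No list of regions prone to artefact signal was used here.

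The third comparison asked whether targeting Trib1 and adding C/EBPα altered the same sites. Of the 3569 sites gained in Trib1_LSKO, 1832 (51.3%) were also gained in AAV_Cebpa and 57 (1.6%) were lost there. Of the 3661 sites lost in Trib1_LSKO, 605 (16.5%) were lost in AAV_Cebpa and 207 (5.7%) were gained. Independent changes among sites of the same control state would give 1155 sites gained in both and 116 lost in both, so the observed numbers were 1.59 and 5.21 times those. These ratios are not comparable with each other. Sites absent from all 4 control lists enter only if a treated list holds them, which raises the number expected gained in both. Over all sites, the corresponding ratios were 2.63 and 3.1. Of the 2701 sites changed in both experiments, 2437 (90.2%) changed in the same direction, with an odds ratio of 93.9 (95% interval 69.1 to 128; Fisher's exact test, with a p too small for the program to represent). Sites are not independent replicates, and the interval covers counting of sites only. The control state of a site limits the directions it can take, so the association was also taken within control states. Among the 37714 sites absent from all 4 control lists, the odds ratio of being gained in both was 3.15 (2.89 to 3.43), and among the 31953 sites called in all 4 it was 12.4 (10.9 to 14) for being lost in both. With Trib1_LSKO and Trib1_WT exchanged, these odds ratios were 0.254 (0.22 to 0.295) and 2.76 (2.07 to 3.68). Independent changes within control states would give an odds ratio of directions of 1.06. Sites called in no list are missing from its number expected gained in both and would lower it. The 1.06 is therefore too high to serve as a firm baseline. With Trib1_LSKO and Trib1_WT exchanged, that value was 0.0114, so it depends on which group is taken as the control. Under the exchange, the 1832 sites gained in both experiments count as lost in the first and gained in the second. Their expected number was then 1741, close to the observed one (1.05 times). The observed odds ratio of directions was 206 (125 to 337) with the strongest 50% of each list and 165 with a signal of at least 10. With presence from the strongest 50% and absence from the full list, the observed odds ratio was 357 (114 to 1120), over 387 sites. The odds ratio of directions was lowest, 15.3, without Trib1_WT replicate 2, followed by 25.4 without Trib1_LSKO replicate 1, 43 without Trib1_WT replicate 1 and 44.8 without AAV_Cebpa replicate 1. Leaving out AAV_Null replicate 1 or 2 gave 57.6 or 59.5.

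The same relation was read in each library by itself. Sites gained in AAV_Cebpa were called in 31.4% (95% Wilson interval 30.8% to 32.0%) and 29.4% (28.8% to 30%) of cases in the 2 Trib1_LSKO libraries. In the 2 Trib1_WT libraries they were called in 19.9% (19.3% to 20.4%) and 17.8% (17.3% to 18.3%). Sites lost in AAV_Cebpa were called less often in Trib1_LSKO, 46.7% ± 10.7, than in Trib1_WT, 66.9% ± 6.3 (SD, n = 2 each). Sites gained in Trib1_LSKO were called in 71.1% and 80.4% of cases in AAV_Cebpa and in 18.7% and 17.1% in AAV_Null. The AAV_Cebpa lists held 59564 and 80394 peaks and the AAV_Null lists 46348 and 49052, over 113353 sites. Longer lists call more of any set of sites, which raises the shares in AAV_Cebpa. Sites lost in Trib1_LSKO were called in 28% ± 11.6 in AAV_Cebpa and 43.4% ± 2.1 in AAV_Null. Sites gained or lost in one experiment were chosen partly by its control lists, which resemble the control lists of the other, so part of these differences comes with that choice. In each of these 4 readings the groups did not overlap, and each had an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries can give.

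The strongest sites gained in both experiments were chromosome 5, 92050320 to 92050538 (mean percentile 98.2 over the 4 treated libraries), chromosome 1, 63841012 to 63841219 (98.1), chromosome 15, 59538695 to 59538934 (97.6), chromosome 15, 59613931 to 59614142 (94.6), and chromosome 9, 116100035 to 116100249 (94.3). All 5 were called in the 4 treated libraries and in none of the 4 control libraries. In the AAV_Cebpa lists, the 1832 sites gained in both experiments had a median percentile of 61.6 (interquartile range 40.5 to 80.1). The 20292 sites gained there alone had a median of 40.4 (22.6 to 60.8). In the Trib1_LSKO lists the corresponding medians were 32.4 (17.8 to 48.4) for the shared sites and 24.3 (13.1 to 41.2) for the other 1737. Shared sites had to be called in more lists, which by itself can favour stronger ones. Lost sites were not uniform in this. The 605 sites lost in both had a median of 34.3 in the AAV_Null lists, against 38.1 for those lost in that experiment alone. In the Trib1_WT lists the medians were 31.1 and 22.5.

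Gained sites of AAV_Cebpa were distributed over the chromosomes differently from common sites. Chromosome X held 768 gained sites, 3.47% of all gained against 2.30% of common sites, a ratio of 1.51 (Fisher's exact test, adjusted p = 4.4e-13). It held 2.93% and 3.21% of all peaks in the AAV_Cebpa lists and 2.40% and 2.46% in the AAV_Null lists. Shares were also higher on chromosomes 2, 3 and 16 (ratios of 1.1, 1.11 and 1.14) and lower on chromosomes 7, 8, 11, 17 and 19 (0.89, 0.83, 0.86, 0.82 and 0.76), with the lowest adjusted p of these, 2.3e-06, on chromosome 19. For Trib1_LSKO, gained sites were relatively more frequent on chromosome 2 (ratio 1.22, Fisher's exact test, adjusted p = 0.00815) and lost sites on chromosome X (ratio 1.42, adjusted p = 0.0138). No chromosome passed for the sites lost in AAV_Cebpa, where the lowest unadjusted p was 0.026 (Fisher's exact test), on chromosome 2. These tests count sites as if independent, so their p-values do not measure variation between libraries or animals.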

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

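The signal minimum, the thinning of tags, the 500 bp rule and the block on site counts were chosen after the data had been examined. Of 104 values recomputed under alternatives, 77 were counted as the same, 26 moved and 1 reversed. For differences in peak number and odds ratios, the same means the same direction, though they changed in size. Counts labelled the same lay within 1.5 times the main value, for instance 2580 against 3661 sites lost in Trib1_LSKO with a signal of at least 10. For Jaccard indices and percentiles the same means close to the main value. The 77 include the replicate block and the peaks as deposited, which gave the main values by construction. The reversal was the difference in peak number between Trib1_LSKO and Trib1_WT, 5.0 with a signal of at least 10; the cause was not tested. Window size, the 500 bp rule, autosomes and thinning left all gained and lost counts within 1.5 times their main values, and peaks as deposited gave identical sites because every peak was already 200 bp wide. The strongest 50% of each list gave 2246 gained and 2021 lost sites for Trib1_LSKO and 11343 and 3152 for AAV_Cebpa, and taking presence from the strongest 50% but absence from the full list gave 541 and 428, and 6944 and 1427; fewer peaks entered by construction. Lists of equal length gave 12783 gained and 9713 lost sites for AAV_Cebpa, Jaccard indices between groups of 0.659 and 0.431, and median percentiles of 30 for sites lost in Trib1_LSKO and 59.9 for sites gained in AAV_Cebpa. Leaving out 1 library asks fewer lists to agree, so counts grew: 5432 to 7612 gained and 5527 to 9281 lost for Trib1_LSKO, and 24454 to 40407 gained and 6786 to 12252 lost for AAV_Cebpa. In that range the share of gained among changed sites ran from 36.9% (without Trib1_WT replicate 1) to 57.9% (without Trib1_LSKO replicate 1) for Trib1_LSKO and from 67.2% (without AAV_Null replicate 1) to 85.6% (without AAV_Cebpa replicate 1) for AAV_Cebpa. These shares depend on which group is left with 1 library. Differences in peak number ran from -3934.0 to -937.0 and from 11864.0 to 32694.0, and the odds ratio of shared directions from 15.3 to 74.6. After thinning the differences were -691.5 and 15138.5. The odds ratio was above 1, with Fisher's exact p under the threshold of 0.05, under every alternative run, including 4.65 for the overlap of gained with gained sites over all sites.

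The replicate numbers were not shown to pair the libraries: the labels name no shared day or litter, and replicate differences correlated at 0.032 across sites between Trib1_LSKO and Trib1_WT and at -0.018 between AAV_Cebpa and AAV_Null. With the replicate number as a block, the differences in peak number stayed at -2435.5 and 22279.0 and the counts at 3569, 3661, 22124 and 6043, which the definition of a gained site fixes. The planned tests of gene lists, motifs and promoters were not run, since genes and sequence of mm9 were not used here. Depth limits the weak end of the lists: the weakest peaks held 7 to 12 tags, so the absence of a peak from a list is not absence of binding.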

Other observations

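Distances between sites, the alternatives on thinned tags, the values on chromosome Y, the test of chromosome X against the highest autosome and the exchange of Trib1_LSKO and Trib1_WT were chosen after the results had been seen. Sites gained in AAV_Cebpa lay farther from the common binding sites than lost sites did. Their median distance to the nearest site called in all 4 libraries was 17.4 kb (interquartile range 5.6 to 53.3), against 10.3 kb (3.6 to 29.8) for lost sites, and 9.4 kb from one common site to the next. Within 2 kb of a common site were 11.4% of gained and 15.0% of lost sites (odds ratio 0.724, Fisher's exact p = 3.3e-14, which covers counting of sites only). A peak of the opposite group lay within 500 bp of 3.8% of gained and 10.5% of lost sites. Whether shifted positions of called peaks contribute to the difference was not tested. In Trib1_LSKO the medians were 10.2 kb for gained and 12 kb for lost sites, with 16.0% and 15.1% within 2 kb (odds ratio 1.08, Fisher's exact p = 0.27).

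The Trib1_WT lists held 13 and 14 peaks on chromosome Y and the Trib1_LSKO lists 9 and 12, while all 4 lists of the second experiment held 0, which allows a share of up to 0.00373% to 0.00647% of peaks against 0.0180% to 0.0256% in the first. Chromosome X held 2.04% to 2.28% of peaks in the 4 Trib1 libraries, 2.40% and 2.46% in AAV_Null, and 2.93% and 3.21% in AAV_Cebpa.

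The agreement in direction between sites changed by targeting Trib1 and sites changed by added C/EBPα (odds ratio 93.9) was weighed against 4 explanations without a shared effect. Depth would lower it after thinning of tags, and it was 104 there. Chance calls of weak sites would lower it among strong peaks, and it was 206 with the strongest 50% of each list. Absence was read from the shortened lists too, so sites near the new cut remain and the 206 cannot decide. With presence from the strongest 50% and absence from the full list it was 357 (95% interval 114 to 1120). That value argues against chance calls of weak sites for the 387 sites it covers. Similar control lists or easily called sites would give associations as high with Trib1_LSKO and Trib1_WT exchanged. The odds ratios were then 0.254 for gained and 2.76 for lost sites against real ones of 3.15 and 12.4. Sites called in no list are missing from the first of these and not from the second. The odds ratio of directions expected from control states was 1.06 with the real roles and 0.0114 with the exchanged ones. Both would be lower if sites called in no list were counted. The exchange therefore does not settle how much of the agreement comes with the control states. Other splits of the libraries gave odds ratios, or their inverses, of at most 10.2, which came from setting the first against the second replicates of the Trib1 groups; the 9 pairs of splits, the real one included, are too few for a share under 0.05. A shared effect of both perturbations on C/EBPα may underlie the agreement, as an untested hypothesis. A general rise in the number of bound sites was not seen in the full Trib1_LSKO lists, where gained sites were 49.4% of changed sites. These lists held 51574 peaks on average against 54009 in Trib1_WT, whose replicate 2 was deeper (1.93) than both Trib1_LSKO libraries. Gained sites were 54.3% of changed sites after thinning and 57.6% with a signal of at least 10, but 36.9% without Trib1_WT replicate 1. The 36.9% cannot decide, because lost sites then need a peak in only 1 Trib1_WT list. A small rise is therefore not excluded.

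The excess of gained over lost sites in AAV_Cebpa (3.66) was weighed against depth, a flatter signal and a single long list. After thinning tags to the shallowest library it was 2.78, with gained sites at 73.6% of changed sites (95% exact binomial interval 73.0% to 74.1%). Of the gained sites, 31.4% (95% exact binomial interval 30.8% to 32.0%) lay in the strongest 50% of both AAV_Cebpa lists, but so did 23.6% of lost sites in the AAV_Null lists, which a flatter signal in AAV_Cebpa would not bring in, so the bound of 5% set in advance does not separate the cases and a flatter signal stays open. Without AAV_Cebpa replicate 2, whose list is the longest, the ratio was 2.6. The thinned value argues against depth as the whole cause. The value without the longest list cannot decide on a single long list. Gained sites then need a peak in only 1 treated list, while lost sites still need both control lists. The ratio of 1.32 with lists of equal length decides nothing either, since that setting moves gained and lost sites towards balance by construction. A more efficient immunoprecipitation may contribute beside a biological effect of the vector.

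The relative abundance of chromosome X among sites gained in AAV_Cebpa (ratio 1.51) may have a technical source. It was present after thinning of tags, where chromosome X held 2.90% of gained and 2.13% of common sites (odds ratio 1.37, Fisher's exact p = 2.6e-07), which argues against depth as the whole cause. A difference in sex or X dosage between AAV_Null and AAV_Cebpa cannot be told apart from an effect of the vector by the ratio of chromosome X to the highest autosome, which was 1.33, too close to the autosomes to decide. The absence of peaks on chromosome Y from both groups gives no sign of such a difference, though the lists may lack that chromosome for other reasons. The lower shares on chromosomes 8, 11, 17 and 19 show that the departure is not limited to chromosome X.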
